A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

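Root RNA from 4 samples was measured, 2 biological repeats without nitrogen and 2 with 2.5 mM glutamine for 30 min. Per the labels' protocols, total RNA was extracted with phenol, biotinylated cRNA was prepared from 10 ug of it, and each sample was hybridised to a GeneChip Rice Genome Array. The authors deposited 1 intensity per probe set and array on a linear scale. GCOS and RMA are named in the submitters' processing notes, without version or role, and how the values were summarised and scaled is not given in the sources used here. The values ran from 2.9 to 21202.3, and the arrays' distributions were not identical. Whether a quantile normalization had been applied before the values were summarised is not known. No detection calls were used, and how far a dim probe set lies above background is therefore unknown.

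Intensities under 1 would have been raised to 1, which applied to none, and log2 was taken with no further normalization. The 123 control probe sets were left out of all tests and used only to describe the arrays. The platform's annotation gave 1 gene for 22436 probe sets, several for 95 and none for 34727. All 22436 were matched by gene number to a RefSeq gene table of assembly ASM3414082v1, whose symbols and synonyms gave the names and the members of the gene lists. The matched probe sets stand for 17905 genes, of which 2457 carry a name other than a locus or clone number. Probe sets with several genes were not named.

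Groups were compared with limma 3.58.1 (R 4.3.3) by lmFit and eBayes with the group as the single term, and p-values, two-sided, were adjusted by the Benjamini-Hochberg method over all 57258 probe sets with a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, the one with the highest mean over the 4 arrays, and adjusted over the 37 lists with 3 or more genes, with an estimated correlation as an alternative. Fry, which tests a list against no change and not against the other genes, was run beside it. A count without a variance model took probe sets with a fold of at least 2 between group means and no overlap of the groups, and was repeated for the other splits of the 4 arrays. The tests, the lists' subjects and the alternatives were fixed before the data were examined, except for 5 alternatives added later, with the omission of each array in turn counted as 1. The lists had been written as locus numbers and description words, neither of which could be matched to the gene table, so the 42 lists were rewritten as patterns on gene symbols and synonyms after the table was seen and before any expression value was tested. This left 5 lists with under 3 genes untested and made the others shorter than planned.

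The rule for named genes took the 15 named genes with the largest rise and the 15 with the largest fall among those that passed without overlap. None passed, so places were filled by the smallest unadjusted p among probe sets with a fold of at least 2 and no overlap, which gave 15 genes higher and 2 lower. Up to 4 members per list with the smallest p, and a fixed set of nitrogen response genes whatever their values, completed the rule. Of this fixed set, the LBD37-like genes, IRO2, ASN1, NADH-GOGAT1 and NRT2.1 were not matched by name and are not analysed here. For genes with several probe sets, the one with the smallest p is given for genes named by rank and the one with the highest mean for list members and for the fixed set.

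The scripts were tested on simulated data for plus glutamine against minus N over 57258 probe sets, with 200 changed. With an SD of 0.1 between arrays, all 67 probe sets changed 2-fold, all 67 changed 4-fold and all 66 changed 8-fold were called. With the spread of the real arrays, 0 of 67, 0 of 67 and 0 of 66 were called. With the replicate number as a further term, 2, 61 and 66 of them were called where the simulation kept the difference between numbers, and 0 where the spread was independent. A shift of 0.5 log2 planted in the 32 genes of the jasmonate list gave an adjusted p of 1.2e-07 with the preset correlation and 0.78 with an estimated one over 17905 genes. Alternatives covered the replicate number as a further term, leaving out each array, a trended and robust variance prior, median centring, quantile normalization, leaving out the dimmer 50% of probe sets, a floor at the 20th percentile, probe sets prone to cross-hybridisation, fold minimums and 1 value per gene. Figures were drawn with matplotlib 3.10.9.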

Results

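Gene expression was measured in roots of rice seedlings (Oryza sativa japonica, cultivar TNG67) with the GeneChip Rice Genome Array, a single-colour oligonucleotide array on which each probe set gives 1 intensity per hybridised sample. Seedlings germinated for 3 days in the dark and then grew for 2 weeks in hydroponic solution without nitrogen. At 17 days of age they were moved for 30 min either to fresh solution without nitrogen (the minus N group, 2 arrays) or to solution with 2.5 mM glutamine, an amino acid that roots take up as a nitrogen source (the plus glutamine group, 2 arrays). Each group held 2 biological repeats, numbered 1 and 2 in both groups. The table of values held 57381 probe sets, of which 57258 were not array controls. The median intensity of these was 19.9 and 21.7 in the minus N arrays and 19.7 and 22.2 in the plus glutamine arrays, for replicates 1 and 2 in that order. With 2 arrays per group, the number of arrays limits the precision of each value below.

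The arrays resembled each other more by replicate number than by treatment. Across probe sets, log2 intensities correlated at r = 0.995 between the arrays numbered 1 of the 2 groups and at r = 0.990 between those numbered 2, against r = 0.975 between the minus N repeats and r = 0.983 between the plus glutamine repeats. These correlations are across probe sets, which are not independent replicates. The control probe sets for Gapdh, a glycolytic enzyme used to judge RNA quality, followed the same grouping. The ratio of the 3′ to the 5′ Gapdh intensity was 6.94 in minus N replicate 1 and 6.20 in plus glutamine replicate 1, and 4.32 and 4.43 in the arrays numbered 2. Because the numbers were equally represented in both groups, the difference between groups is given below also within each number for the called lists and for part of the genes.

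The comparison of plus glutamine with minus N roots asks which transcripts respond to glutamine within 30 min in roots starved of nitrogen. Of the probe sets at least 2-fold apart without overlap, 28 of the 225 higher and 2 of the 19 lower with glutamine carry a gene name, so the genes below are a small part of them. NAC5, a stress-responsive transcription factor of the NAC family, had a log2 intensity of 5.46 ± 0.16 (SD, n = 2) without nitrogen and 7.41 ± 0.16 (SD, n = 2) with glutamine, a 3.87-fold difference (log2 difference 1.95, SE 0.23). Its other probe sets had log2 differences of 1.75 and 2.33. DREB1A, a transcription factor that binds the dehydration-responsive element, stood at 6.55 ± 0.28 (SD, n = 2) and 8.61 ± 0.49 (SD, n = 2), a 4.17-fold difference (log2 difference 2.06, SE 0.32). The difference was alike within both replicate numbers, at 2.18 and 1.73 for NAC5 and at 1.91 and 2.21 for DREB1A. NAC5 and DREB1A were known beforehand as genes reported for these arrays, so their values are not independent evidence.

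Among the other genes at least 2-fold apart without overlap, CIPK14, a protein kinase that acts with calcineurin B-like calcium sensors, was 2.47-fold higher with glutamine (log2 difference 1.31, SE 0.22). RR6, a response regulator of cytokinin signalling, stood at 7.77 ± 0.34 (SD, n = 2) without nitrogen and 9.27 ± 0.12 (SD, n = 2) with glutamine, a 2.83-fold difference (SE 0.26 on the log2 scale). WRKY71 and WRKY24, transcription factors of the WRKY family, differed by 1.05 (SE 0.24) and 1.33 (SE 0.37) on the log2 scale. Another probe set of WRKY71 differed by 1.89 (SE 0.57), with its minus N repeats at 6.53 and 4.85. JAZ9 and JAZ13, repressors of jasmonate signalling, differed by 1.61 (SE 0.47) and 1.24 (SE 0.34), and the basic helix-loop-helix factor BHLH148 by 1.13 (SE 0.27). ERG1, PHT3, a gene named only as chitinase, Chib3H-h, PIN5 of the auxin efflux carrier family and Agglutinin completed the 15 genes named for higher values, with folds between 2.03 for PIN5 and 2.82 for PHT3 and the chitinase gene. Some of these differences rested more on the arrays numbered 2 than on those numbered 1. JAZ9 differed by 0.98 within number 1 and by 2.25 within number 2, and its minus N repeats stood at 8.74 and 7.35. The same pair of differences was 0.63 and 2.03 for WRKY24, 0.86 and 2.00 for ERG1 and 0.82 and 2.18 for PHT3, against 1.44 and 1.17 for CIPK14 and 1.35 and 1.65 for RR6. Without minus N replicate 2 the log2 difference was 0.95 for ERG1, 0.92 for PHT3, 0.91 for the chitinase gene, 0.91 for JAZ9 and 0.81 for JAZ13, and without minus N replicate 1 it was 0.69 for Agglutinin. In the other direction 2 named genes met the same criteria. DREB1G, of the same transcription factor family as DREB1A, was 2.08-fold lower with glutamine (log2 difference -1.05, SE 0.34) and Hox28, a homeobox gene, 2.05-fold lower (log2 difference -1.04, SE 0.34). DREB1G differed by -0.47 within number 1 and -1.64 within number 2, and Hox28 by -0.43 and -1.64, and without minus N replicate 2 the log2 differences were -0.65 and -0.64. None of these genes passed the planned test over all probe sets, in which the lowest adjusted p of limma's moderated test was 1. Only a setting added later, with the replicate number as a further term and a trended and robust prior, called NAC5, DREB1A, CIPK14 and RR6.

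**Figure D1:**
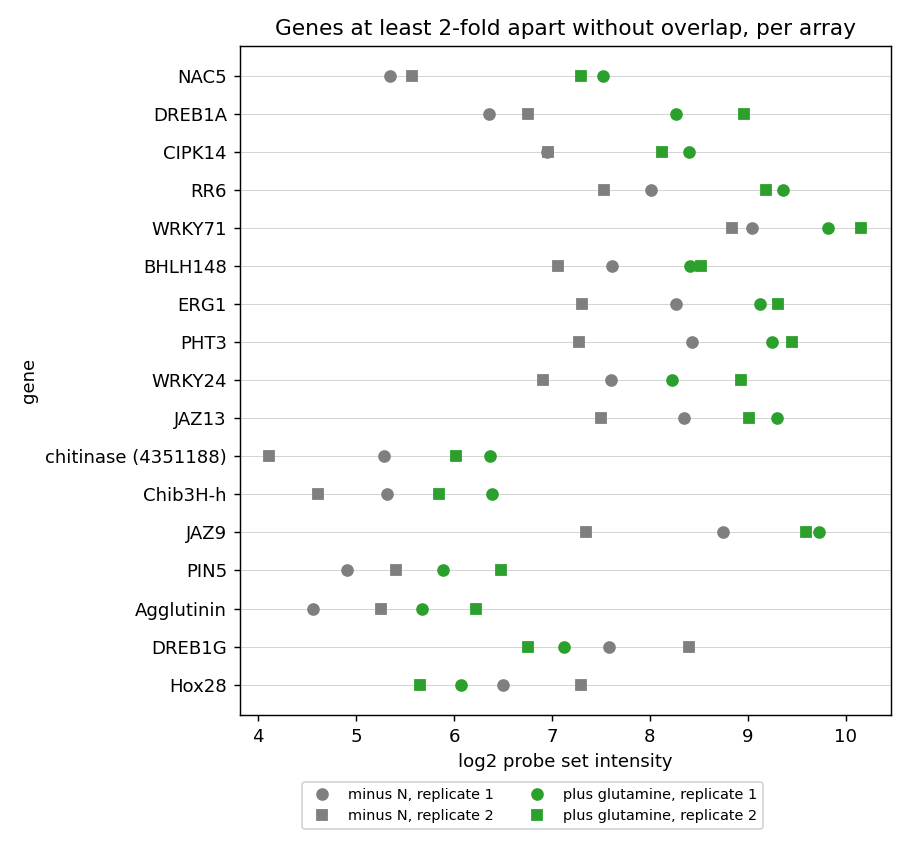
Log2 probe set intensity (horizontal axis) of the 15 named genes that were higher and the 2 that were lower with glutamine, with 1 point per array; grey points are minus N and green points plus glutamine, circles replicate 1 and squares replicate 2. The green points of NAC5 lie at 7.52 and 7.30 and its grey points at 5.34 and 5.57, and in no gene do the colours overlap.

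The gene lists hold only genes matched by symbol or synonym. Of the 17905 genes 2457 carry a name, so a list can lack members of its family. With a preset correlation between genes, camera called the lists of jasmonate synthesis and signalling, WRKY and NAC transcription factors and pathogenesis-related genes higher with glutamine than the rest of the measured genes. Each of these lists had an adjusted p of 0.67 with an estimated correlation, and WRKY and NAC also lost the call without minus N replicate 2 (adjusted p = 0.36 and 0.075). Of the 32 genes of jasmonate synthesis and JAZ repressors, 13 had both plus glutamine arrays above both minus N arrays and 2 had both below, where chance gives 16.7% in each direction. The median log2 difference of this list was 0.21 within number 1 and 0.43 within number 2, and camera gave an adjusted p of 3.4e-10. The same test also called this list in the crossed split (camera adjusted p = 0.0077). That split sets minus N replicate 1 and plus glutamine replicate 2 against the other arrays, so treatment cancels. A call of this list at the preset correlation therefore does not require a treatment difference. Its leading members were AOS1, an allene oxide synthase of jasmonate synthesis, with a log2 difference of 0.95 (SE 0.23), JAZ13, JAZ9, and the lipoxygenase gene LOX2.1 at 0.96 (SE 0.29). The adjusted p was 0.67 with an estimated correlation between genes, and none of the 32 genes passed over all probe sets or adjusted over the list alone. With an estimated correlation, camera gave 0.78 for a shift of 0.5 log2 planted in this list in simulated arrays, so the value of 0.67 cannot decide.

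The 6 WRKY genes had a median log2 difference of 1.19, with 0.34 within number 1 and 1.67 within number 2 (camera adjusted p = 8.2e-06), with 3 higher without overlap, 0 lower, and 2 passing when adjusted over the list alone. Next to WRKY71 and WRKY24, WRKY51 differed by 0.55 (SE 0.24) and OsWRKY76 by 1.68 (SE 1.28). The minus N repeats of OsWRKY76 lay at 8.30 and 4.35, and without minus N replicate 2 OsWRKY76 differed by -0.30 and WRKY51 by 0.35. Without minus N replicate 1 OsWRKY76 differed by 3.65, and without plus glutamine replicate 1 by 1.08. The adjusted p of the list was 0.67 with an estimated correlation and 0.36 without minus N replicate 2. Of 8 NAC genes, 4 were higher without overlap and 0 lower, and the list's median difference was 0.58, with 0.25 within number 1 and 0.70 within number 2 (camera adjusted p = 0.00021). NAC5 was the single member that passed when adjusted over the list alone. It was known beforehand, so neither that pass nor the camera call of the list, which includes it, is independent evidence. NAC45 differed by 0.89 (SE 0.33), NAC068 by 1.06 (SE 0.50) and NAC067 by 0.78 (SE 0.39). Without minus N replicate 2, NAC068 differed by 0.31 and NAC067 by 0.24, without minus N replicate 1 by 1.81 and 1.32, and without plus glutamine replicate 2 NAC45 differed by 0.56. The adjusted p of the NAC list was 0.67 with an estimated correlation and 0.075 without minus N replicate 2. In the list of pathogenesis-related and phenylpropanoid genes, 7 of 18 genes were higher without overlap and 0 lower, with a median difference of 0.21, and of 0.19 within each number (camera adjusted p = 2.2e-05; adjusted p = 0.67 with an estimated correlation). Those that led it were chitinase genes, enzymes that degrade chitin: the gene named only as chitinase, Cht2 with a log2 difference of 0.78 (SE 0.25) and Cht-3 with 0.52 (SE 0.24). With them stood RIXI, a xylanase inhibitor gene, with 0.60 (SE 0.21) at mean intensities of 6.0 and 9.1. Without plus glutamine replicate 2 Cht-3 differed by 0.32, and without minus N replicate 2 the chitinase gene by 0.91. RIXI lies among the dimmer probe sets, and its difference was 0.36 with a floor at the 20th percentile. None of its members passed adjusted over the list alone.

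For 3 further lists the shift passed the threshold more narrowly. The 6 glutathione S-transferase genes, detoxification enzymes, had a median difference of 0.34, with 0.17 within number 1 and 0.33 within number 2 (camera adjusted p = 0.028), with GSTZ5 at 0.39 (SE 0.23) and GST1 at 0.33 (SE 0.22), and 0 passed adjusted over the list alone. Without plus glutamine replicate 2 they differed by 0.22 and 0.19. The adjusted p of the list was 0.98 with an estimated correlation, and it lay between 0.065 and 0.34 when any 1 of the arrays was left out. The 18 cytokinin response regulators and cytokinin oxidases had 6 members higher without overlap and 0 lower, at a median difference of 0.05, with 0.10 within number 1 and 0.05 within number 2 (camera adjusted p = 0.039). The adjusted p of this list was 0.99 with an estimated correlation, 0.058 with a trended and robust prior, 0.059 after median centring, 0.070 after quantile normalization, 0.061 without dim probe sets, 0.075 with a floor, and between 0.11 and 0.35 without any 1 array. RR6 passed adjusted over the list alone, and the cytokinin oxidase gene CKX4, whose enzyme degrades cytokinin, differed by 0.78 (SE 0.23). The 23 cytosolic ribosomal protein genes were slightly lower with glutamine, with 8 lower and 1 higher without overlap and a median difference of -0.12, with -0.07 within number 1 and -0.14 within number 2 (camera adjusted p = 0.039). RPL7A-2 differed by -0.24 (SE 0.20) and RPL5 by -0.27 (SE 0.25; -0.04 without minus N replicate 2 and -0.50 without minus N replicate 1), and 0 genes passed adjusted over the list alone. The adjusted p of the list was 0.99 with an estimated correlation and 0.15 after quantile normalization. The direction of the ribosomal list turned, at an adjusted p of 0.91 and 0.81, without minus N replicate 1 or without plus glutamine replicate 2. Of the 7 called lists, 0 kept the call with an estimated correlation. That test also missed a shift of 0.5 log2 planted in simulated arrays (camera adjusted p = 0.78), so the lost calls do not decide for or against a shift.

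**Figure D2:**
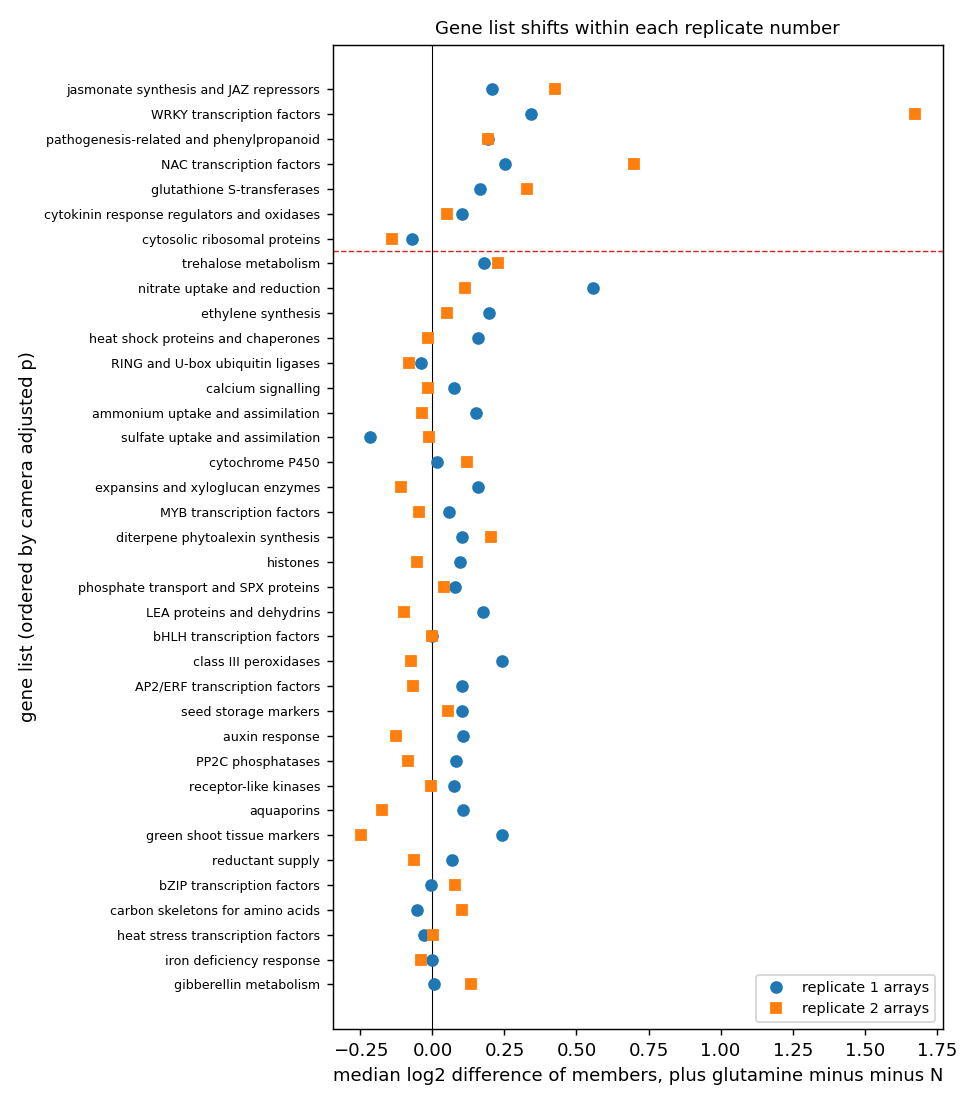
Median log2 difference between plus glutamine and minus N (horizontal axis) over the members of each tested gene list, within the arrays numbered 1 (circles) and numbered 2 (squares), with the lists ordered by the adjusted p of camera and the 7 called lists above the dashed line. The jasmonate list lies at 0.21 and 0.43 and the ribosomal list below 0 in both.

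Genes of nitrogen uptake and assimilation showed no shift that passed the test. The 17 genes of ammonium uptake and assimilation had a median log2 difference of 0.06 (camera adjusted p = 0.23), and the 4 genes of nitrate uptake and reduction one of 0.34 (adjusted p = 0.15). GLN1-2, a cytosolic glutamine synthetase also named GS1;2, stood at 11.85 ± 0.60 (SD, n = 2) without nitrogen and 11.91 ± 0.47 (SD, n = 2) with glutamine. The ammonium transporter genes AMT1-1 and AMT1-2 differed by 0.14 (SE 0.40) and 0.57 (SE 0.51). GDH2, a glutamate dehydrogenase gene, differed by 0.63 (SE 0.24), and the nitrate transporter gene NRT2.2 by 1.06 (SE 0.56). These differences varied with the replicate number. AMT1-2 differed by 0.88 within number 1 and 0.26 within number 2, and the minus N repeats of NRT2.2 stood at 5.86 and 7.58. NRT2.2 differed by 0.20 without minus N replicate 1 and by 1.92 without minus N replicate 2, and GDH2 by 0.41 without plus glutamine replicate 2. Over the fits that leave out 1 array, GLN1-2 ranged from -0.37 to 0.48, AMT1-1 from -0.39 to 0.66 and AMT1-2 from -0.11 to 1.24. The call depended on single arrays. Without minus N replicate 2 the adjusted p was 0.0071 for the ammonium list and 3.1e-05 for the nitrate list, without minus N replicate 1 the direction of both turned (adjusted p 0.71 and 0.79), and without plus glutamine replicate 1 the nitrate list had an adjusted p of 0.044.

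The other lists did not pass either, and the 30 tested lists that were not called had camera adjusted p-values between 0.12 and 0.99. For the 79 calcium signalling genes the adjusted p was 0.17, with 12 higher and 11 lower without overlap. CML20 and CML15, calmodulin-like genes, differed by 0.70 (SE 0.21) and 1.08 (SE 0.39). The 12 AP2/ERF factors went both ways, with DREB1A higher and DREB1G and DREB1E lower, and had an adjusted p of 0.85. DREB1E had a log2 difference of -0.80 (SE 0.37), with -0.11 within number 1 and -1.50 within number 2. The 41 auxin response genes had an adjusted p of 0.90, with the auxin-conjugating enzyme gene GH3-8 at 0.80 (SE 0.23). Heat stress transcription factors had an adjusted p of 0.95, iron deficiency genes 0.95, aquaporins 0.90, phosphate transport genes 0.67 and trehalose metabolism genes 0.12. Among markers of other tissue, the 8 genes of green shoot tissue had an adjusted p of 0.90 and the 8 seed storage genes 0.87. Some of these lists were called higher in single alternatives: green shoot tissue and expansin genes without minus N replicate 2 (adjusted p = 0.019 for both), calcium signalling without plus glutamine replicate 2 (0.049) and trehalose metabolism without dim probe sets (0.034). The median log2 intensity of the green markers was 9.52 and 10.52 in the minus N arrays and 9.81 and 10.11 in the plus glutamine arrays, for numbers 1 and 2, so it was lower in the arrays numbered 1. The median of all genes was 7.16 and 7.46 in the minus N arrays and 7.24 and 7.44 in the plus glutamine arrays. Green markers thus lay above the typical gene in every array, and seed storage markers below it, at medians from 2.70 to 3.11. Whether the root samples held green tissue was not tested.

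Over all 57258 probe sets, limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower. At an unadjusted p under 0.05 there were 505 probe sets, 453 higher and 52 lower, where chance alone gives 2862.9. This fit counts the difference between replicate numbers as spread. With the replicate number as a further term, limma gave 2480 probe sets at an unadjusted p under 0.05 and again called 0. A setting added later, with a trended and robust prior as well, called 24 higher and 0 lower. On data simulated with the spread of these arrays, the fit with the group alone called none of 66 probe sets changed 8-fold, so the absence of calls in that fit does not bound the size of change. A fold of at least 2 between group means with no overlap was found for 225 probe sets that were higher and 19 that were lower with glutamine. Chance gives no overlap in 33.3% of probe sets with 2 arrays against 2, and 16.6% had none here. The same criteria gave 1499 probe sets higher and 766 lower in the arrays numbered 2 against those numbered 1 (809 and 1107 after quantile normalization), and 18 and 13 for the remaining split of the 4 arrays. Within the arrays numbered 1, 129 probe sets were at least 2-fold higher with glutamine and 127 lower, and within those numbered 2, 647 were higher and 338 lower. In both at once, 53 were higher and 1 was lower.

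**Figure D3:**
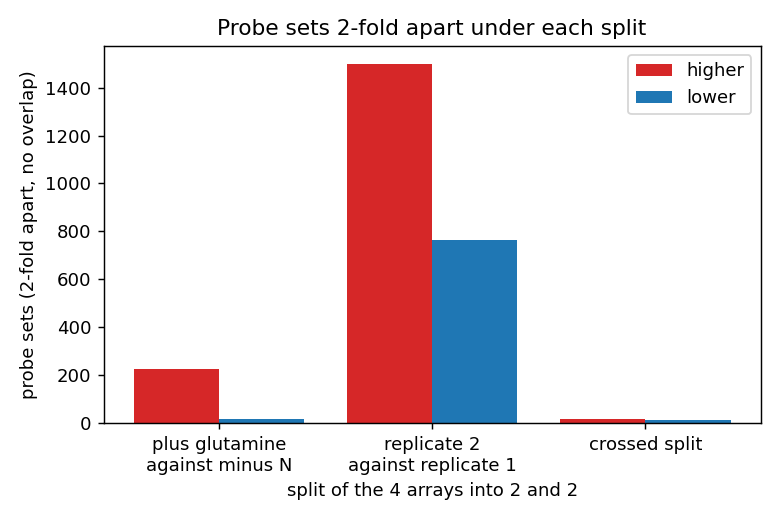
Number of probe sets at least 2-fold apart without overlap (vertical axis, from 0) for each way to split the 4 arrays into 2 and 2, with red bars for higher and blue bars for lower in the first-named side. The treatment split gives 225 and 19, the split by replicate number 1499 and 766, and the crossed split 18 and 13.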

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

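The poly-A spike controls, bacterial transcripts that the platform provides for addition to the RNA before labelling, lie outside the comparison of the groups, and their signal in 1 plus glutamine array was above that of the minus N arrays. Over 36 poly-A probe sets the geometric mean intensity was 153.58 in plus glutamine replicate 2, against 98.6 and 90.5 in the minus N arrays and 78.4 in plus glutamine replicate 1. All 36 probe sets were highest in that array. The hybridisation controls, which are added after labelling, had a geometric mean of 847 there and between 875 and 1048 in the others. Without this array, the count of probe sets at least 2-fold apart without overlap was 312 higher and 57 lower, limma called 0, and 5 gene lists were called higher, 4 of them among those called with all arrays, and 0 lower.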

How the results depend on the processing

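All alternatives were chosen before the data were examined, except the combined settings and those for the count of 2-fold differences that leave out an array, centre the arrays or use pairs. The count of 0 probe sets called in each direction held in every setting tried but one: the replicate block with a trended and robust prior called 24 higher and 0 lower, among them CIPK14, DREB1A, NAC5 and RR6. The replicate block alone called 0, with 2480 probe sets at an unadjusted p under 0.05 and a lowest adjusted p of 0.51. In simulated arrays that kept the difference between numbers, with 200 probe sets changed at once, it called 61 of 67 changes of 4-fold and 66 of 66 of 8-fold. In the real arrays the same limma fit gave DREB1A, which was 4.17-fold higher, an adjusted p of 0.56. The 0 calls of the block therefore do not exclude changes of that size. Leaving out any 1 array also called 0. Arrays of the same number deviated from their group means together, with a correlation of 0.67 across probe sets, but the labels name no shared batch and 2 pairs do not establish pairing. The 6 lists called higher became 0 with an estimated correlation, and the count ranged from 4 to 6 without single arrays. These are not the same lists: 2 of the 6, jasmonate and pathogenesis-related, kept the call without minus N replicate 2, where 4 others gained it, and 4 of the 6 kept it without each other array. The 1 list called lower became 0 with an estimated correlation, median centring or quantile normalization, and 0 to 1 without single arrays. Fry asks another question, whether a list changed at all and not whether it changed more than other genes. Its directional form called 0 lists higher and 0 lower. Its mixed form, which has no direction, called 1, the NAC list, which includes NAC5, a gene known beforehand. With the replicate block the cytokinin list had an adjusted p of 0.16, and no other called list lost its call. The 225 higher and 19 lower probe sets became 699 and 133 at a fold of 1.5, 49 and 0 at a fold of 3, and 53 and 1 when both same-numbered pairs had to differ 2-fold, changes that follow from the stricter or looser criterion. Without single arrays they ranged from 312 to 766 higher and from 57 to 421 lower, since 1 array against 2 overlaps less often. The share of higher, 92.2%, fell to 64.5% without minus N replicate 1, 49.5% without minus N replicate 2 and 71.9% without plus glutamine replicate 1.

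Direction turned only when an array was left out, and the cause was not tested. A group of 1 array is assumed to vary like the other group. Over the fits that leave out 1 array, the log2 difference ranged from -0.37 to 0.48 for GLN1-2, -0.39 to 0.66 for AMT1-1, -0.11 to 1.24 for AMT1-2, -0.11 to 0.78 for NAR2.2, -0.24 to 0.92 for NIA1 and -0.11 to 0.84 for GSTF1, each lowest without minus N replicate 1. It was also -0.27 for GLN1-2 and -0.06 for AMT1-1 without plus glutamine replicate 2. It ranged from -1.08 to 0.88 for NRT2.3, with 0.53 without plus glutamine replicate 1, and from -0.30 to 3.65 for OsWRKY76, lowest without minus N replicate 2. The adjusted p ranged from 0.0022 to 0.91 for the ribosomal list, 0.0071 to 0.94 for the ammonium list and 3.1e-05 to 0.79 for the nitrate list. Direction turned without minus N replicate 1 in all of these lists (0.91, 0.71 and 0.79) and without plus glutamine replicate 2 in the ribosomal list (0.81). The other 476 of 487 alternatives for 49 probe sets kept direction and side of the threshold.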

Other observations

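The tests that weigh explanations here were set up after the pattern was seen, though the quantile normalization and the dim filter for treatment, the fits without 1 array and the estimated correlation had been planned, and the shares of genes by replicate number were also chosen after. Of the 21 measured genes of ammonium and nitrate uptake and assimilation, 17 (81.0%) were higher in replicate 2 than in replicate 1 in both groups, against 56.3% of all 17905 genes. Other lists had shares as high, with 7 of 8 green shoot tissue markers, 14 of 17 RING and U-box ligases, 13 of 16 phosphate transport genes and 6 of 6 reductant supply genes, so the nitrogen genes are not set apart. A larger difference between numbers than between treatments was found in 14 of them (66.7%), and in 73.7% of all genes. The nitrate transporter gene NRT2.3 was higher in replicate 2 by 1.96 on the log2 scale without nitrogen and by 1.26 with glutamine, and the ammonium transporter gene AMT3-2 by 1.30 and 1.00. GLN1-2 differed by 0.85 and 0.66 and Fd-GOGAT, a glutamate synthase gene, by 0.83 and 0.83. The median of all probe sets was itself higher in replicate 2, by 0.14 and 0.17. Neither list passed in this direction (camera adjusted p = 0.19 for both, and 0.89 with an estimated correlation). Histone genes and cytosolic ribosomal protein genes were lower in replicate 2, with median log2 differences of -0.14 and -0.29 for 6 histone genes and of -0.06 and -0.11 for 23 ribosomal genes (camera adjusted p = 0.026 and 0.011). Both had an adjusted p of 0.89 with an estimated correlation.

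The arrays grouped by replicate number. A limma fit of replicate 2 against replicate 1 called 8498 probe sets, against 0 for the treatment, which points to a structure of the samples that the labels do not name. Between the numbers, 2265 probe sets were 2-fold apart without overlap, and 1916 after quantile normalization, a count 84.6% as large. A count of that size argues against array scaling as the whole source. These are not all the same probe sets, since 1499 higher and 766 lower became 809 and 1107. How many of the 2265 kept their difference was not counted, and the direction of the majority depends on scaling. RNA integrity or labelling length remains a candidate explanation: the lowest Gapdh 3′ to 5′ ratio of the arrays numbered 1 was 1.40 times the highest of those numbered 2, and the actin controls gave 1.02 and 1.24. How much of the difference it accounts for is open, as are plants, days and processing that differed between the repeats, and no biological explanation was tested.

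Of the 244 probe sets at least 2-fold apart without overlap between treatments, 225 were higher with glutamine. Array scaling is argued against as the whole source, since the share of higher was 92.1% after quantile normalization. Among the brighter 50% of probe sets 215 were higher and 19 lower, a share of 91.9%, so the excess does not come from the dimmer 50%. Background as a source stays open, because no detection calls were used and the cut may lie near background. Among probe sets 2-fold apart in both same-numbered pairs 87.1% went the same way, where noise would go either way, but r was 0.06 over all probe sets, and in the crossed pairs, which also hold the difference between the numbers, 71 were higher in both, 2 lower and 1306 opposite. The 3 splits of 4 arrays are too few for a share under 0.05: 2 of the 3 splits, the real one included, gave a count as large, and the highest other, 2265, was the split by replicate number. Transcripts that rise early after glutamine supply may account for the excess as a hypothesis, but within the arrays numbered 1 alone 129 were higher and 127 lower, and the share without minus N replicate 2 was 49.5%.

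The jasmonate list was called higher with glutamine. A difference between replicate numbers is argued against as the whole source, because the lower of the medians within numbers was 0.21 on the log2 scale. An array standing apart stays open: the highest adjusted p without any 1 array was 0.0078, but the crossed split, in which treatment cancels, called this list at an adjusted p of 0.0077. Co-varying genes of one list stay open: the adjusted p was 0.67 with an estimated correlation, but the same test gave 0.78 for a shift of 0.5 log2 planted in simulated arrays, so it cannot be told apart from a shift of the list. A response to glutamine is the biological explanation that the design gives, and it stays open.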
